A study of Mus musculus with 39 samples.

How the data were processed

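Polyadenylated RNA from mouse cerebellum was sequenced in 39 libraries (NextSeq 500, single-end): 19 TRAP libraries, 3 inputs of total cerebellar RNA, 8 libraries of cultured granule cells with DMSO, UNC1999 or no culture, and 9 libraries of cultures with Cre and unaltered or floxed Ezh1. The deposited table holds estimated counts per gene, rounded to whole numbers and not normalized. The submitters' processing notes name Salmon 0.8.2 and the mouse build mm10, without saying what each was used for, and do not state the annotation, how transcripts were summed to genes or any filter. The table has 24100 Entrez gene identifiers, of which 24045 were matched to a symbol and 55 were not (on average 0.0361% of a library's counts). In the 9 Ezh1 libraries 1041 genes are blank, 1012 of them on X, 28 on Y and 1 unmatched, while 12 X and 11 Y genes hold values. The reason is not stated, and blank genes were left out of the fits of those libraries. Total counts ran from 12.1 to 38.5 M per library. Reads carry no molecular identifiers, so a bound from counts covers counting error only.

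Groups, comparisons, gene lists, tests, the rule for naming genes and the alternatives listed below without the word added were chosen before the data were examined. Libraries were grouped by their labels. The 4 TRAP groups were fitted together, as were the 4 culture groups. The 15 Neurod1 TRAP libraries and 3 inputs were fitted with age as a factor, because each age has 1 input. The Ezh1 cultures were fitted alone, and the difference between the UNC1999 and the Ezh1 cKO effect was a contrast in a fit of 13 libraries, none shared by the 2 effects. Each fit used edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10, minimum total 15), TMM scaling, and robust quasi-likelihood tests, with Benjamini-Hochberg adjustment over the genes of a comparison and calls at an adjusted p under 0.05. All tests are two-sided. There are 11 such comparisons. After a CPM value ± is the SD over libraries, and after a log2 fold change it is the SE from the fit.

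Gene lists came from general knowledge of the cerebellum. The 13 program lists are granule progenitor and Sonic hedgehog pathway, cell cycle, early differentiation and migration, mature granule cell, synapse, voltage-gated channels, granule transcription factors and chromatin remodelers, Polycomb complexes and H3K27 demethylases, H3K4 methylation enzymes, Hox genes, other silenced developmental regulators, cholesterol synthesis and immediate early genes. The 9 cell type lists are Purkinje cell, GABAergic interneuron, unipolar brush cell, Bergmann glia and astrocyte, oligodendrocyte lineage, microglia, vascular and meningeal, erythrocyte and sex-linked genes. Of the genes in these lists 2 are not in the table, and a list needed 3 measured members. The H3K4 methylation list pools genes for adding the mark with demethylases such as Kdm1a. The list called Polycomb genes below also holds the H3K27 demethylases, and the one called transcription factors also holds the chromatin remodelers. Counts of these lists therefore do not follow a single activity. Each list was set against all other genes with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and again with an estimated correlation, with adjustment over the lists of a comparison. The estimated setting also takes the residual degrees of freedom of the fit, which are few in the culture fits. Of 231 list tests 92 passed at the preset correlation and 0 with the estimated one. The median, the mean and the test of a list differed in sign for some lists, none of which passed. They were unipolar brush cell and sex-linked markers in several comparisons, early differentiation genes between the TRAP lines, against input, under UNC1999 and in Ezh1 cKO, and astrocyte markers for P21 against P7 and DIV2 against DIV0. Others were interneuron markers for DIV2 against DIV0 and in Ezh1 cKO, H3K4 methylation and oligodendrocyte genes for P21 against P12, mature granule cell, synapse, channel, cholesterol and microglia genes in Ezh1 cKO, and progenitor, cell cycle and immediate early genes in the difference of effects.

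Genes named are 6 anchors (Ezh1, Ezh2, Atoh1, Neurod1, Gabra6 and Mki67), up to 4 members per list by adjusted p, the 5 largest rises and falls among called genes with a mean of at least 10 CPM, groups that do not overlap and a named symbol, and up to 10 genes called in both of a pair of comparisons. Rapgefl1, Gapdh, Eno1, Gm4737, Rec8 and AA388235 were named after their values were seen, as were the genes at 0 in a set of Ezh1 libraries.

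Genes that rose or fell from P7 to P21 with a log2 fold change of at least 1 in size (2758 higher, 3364 lower) were tested as sets in the cultures with camera, with adjustment as for the lists. No library is shared between these sets and the cultures. Pearson and Spearman correlations of log2 fold changes were taken across genes. The alternatives were scaling by library size only, DESeq2 size factors in edgeR, no filter on low counts, a filter at 1 CPM in the smallest group, the DESeq2 1.42.0 Wald test (not run on the difference of effects), only the 2 groups compared, replicate number as a block, a log2 fold change of at least 1 in size, each library left out in turn, an estimated correlation, sets at a log2 fold change of 2, sets without cell cycle and other cell type markers, only genes called in both comparisons, and DIV5 against DIV2 in place of DIV5 against DIV0. Added after the data were seen were the 2 sets of Ezh1 libraries as a term, each of those sets alone, the Math1 library pairs alone, the in vivo sets with that term and with each library left out, and a crossed block for DIV5 against DIV2.

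The procedure was tested on simulated data in which 200 genes were changed. Of genes changed 2-fold it recovered 77.6% in the UNC1999 design, 23.9% in the Ezh1 design, 80.6% in the Ezh1 design with the 2 sets as a term and 0% for the difference of effects. Of genes changed 4-fold it recovered 95.5%, 78.8%, 100% and 51.5%. Of genes changed 1.5-fold it recovered 76.1%, 0%, 67.2% and 0%. Unchanged genes made up 23 of 189 calls (12.2%) in the UNC1999 design, above the 5% aimed at, 3 of 71 (4.23%) in the Ezh1 design, 12 of 177 (6.78%) with the 2 sets as a term and 1 of 35 (2.86%) for the difference of effects. For DIV5 against DIV2 they made up 18 of 177 (10.2%), for DIV5 against DIV0 12 of 168 (7.14%), and in the other 6 designs 2.99% to 5.56%. Each design was simulated once. Simulated libraries were drawn independently around the fitted means. The Ezh1 design without the term and the difference of effects thus held no 2 sets of libraries, and no design held wt and cKO libraries paired by number. These rates may therefore not hold for the real Ezh1 libraries.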

Results

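The data follow cerebellar granule cells, the small excitatory neurons of the cerebellum, from dividing progenitors to mature neurons, in the mouse and in primary culture. Polyadenylated RNA was sequenced from 39 libraries. Of these, 19 come from translating ribosome affinity purification (TRAP), in which an EGFP-tagged ribosomal protein L10a made under a cell type promoter is pulled down with the RNA bound to it. The Math1 line (Math1 is Atoh1, the transcription factor of granule cell progenitors) gave 4 TRAP libraries from isolated progenitors at postnatal day 7 (P7). The Neurod1 line, which marks differentiating and mature granule cells, gave 5 TRAP libraries each at P7, P12 and P21 from whole cerebellum, with 1 input library of total cerebellar RNA at each age. Cultures of granule cell progenitors gave 2 libraries each of freshly isolated cells (0 days in vitro, DIV0), DIV2 and DIV5 with the solvent DMSO, and DIV5 with 100 nM UNC1999, an inhibitor of EZH2 and EZH1, the enzymes that place the repressive mark H3K27me3. A last experiment held DIV5 cultures from mice with Atoh1-Cre and either unaltered Ezh1 (wt, 5 libraries) or floxed Ezh1 (conditional knockout, cKO, 4 libraries). Total counts ran from 12.1 to 38.5 M per library. It was 12.1 to 30 M in the Math1 TRAP libraries, 22.5 to 38.5 M in the Neurod1 TRAP libraries and 22.9 to 27.9 M in the inputs. The range was 15.9 to 29.4 M in the cultures with and without UNC1999 and 12.7 to 22.1 M in the Ezh1 cultures. Levels below are means in counts per M (CPM) ± SD over libraries, and log2 fold changes carry ± SE.

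The Neurod1 TRAP series asks how the translated RNA of granule cells changes as they mature in the animal (n = 5 at each age). Between P7 and P21 cell cycle and progenitor genes fell, and genes of mature granule cells and synapses rose. The pull-down did not deplete cell cycle genes against input (6 of 20 higher and 2 lower, camera adjusted p = 0.765). Of 15 progenitor genes 10 were lower and 1 higher than in input (camera adjusted p = 0.143). Whether the falls with age came from fewer progenitors in the tissue or from changes within cells was not tested. Gabra6, the GABA-A receptor subunit typical of mature granule cells, stood at 47.9 ± 14.4 CPM at P7, 685 ± 59.3 at P12 and 1365 ± 120 at P21, a 28.5-fold rise (log2 fold change 4.83 ± 0.33, adjusted p = 1.5e-10). Mki67, the proliferation marker, fell from 171 ± 32.8 to 16.6 ± 2.39 and then 0.216 ± 0.16 CPM, and Atoh1 from 22.1 ± 2.77 to 5.53 ± 2.43 and then 0.0247 ± 0.025 CPM. The pair of H3K27 methyltransferases moved in opposite directions. Ezh2 fell from 102 ± 6.84 over 31.8 ± 3.31 to 7.95 ± 0.52 CPM, 12.9-fold lower (log2 fold change -3.69 ± 0.11, adjusted p = 7.1e-18). Ezh1 rose from 32.2 ± 2.50 over 54.9 ± 1.58 to 93.6 ± 5.2 CPM, 2.90-fold higher (1.54 ± 0.06, adjusted p = 6.5e-16). In the mm10 assembly Ezh1 (Entrez gene 14055) lies on chromosome 11 from 101191115 to 101226463, Ezh2 (14056) on chromosome 6 from 47530274 to 47595270, and Gabra6 (14399) on chromosome 11 from 42306437 to 42321072.

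**Figure D1:**
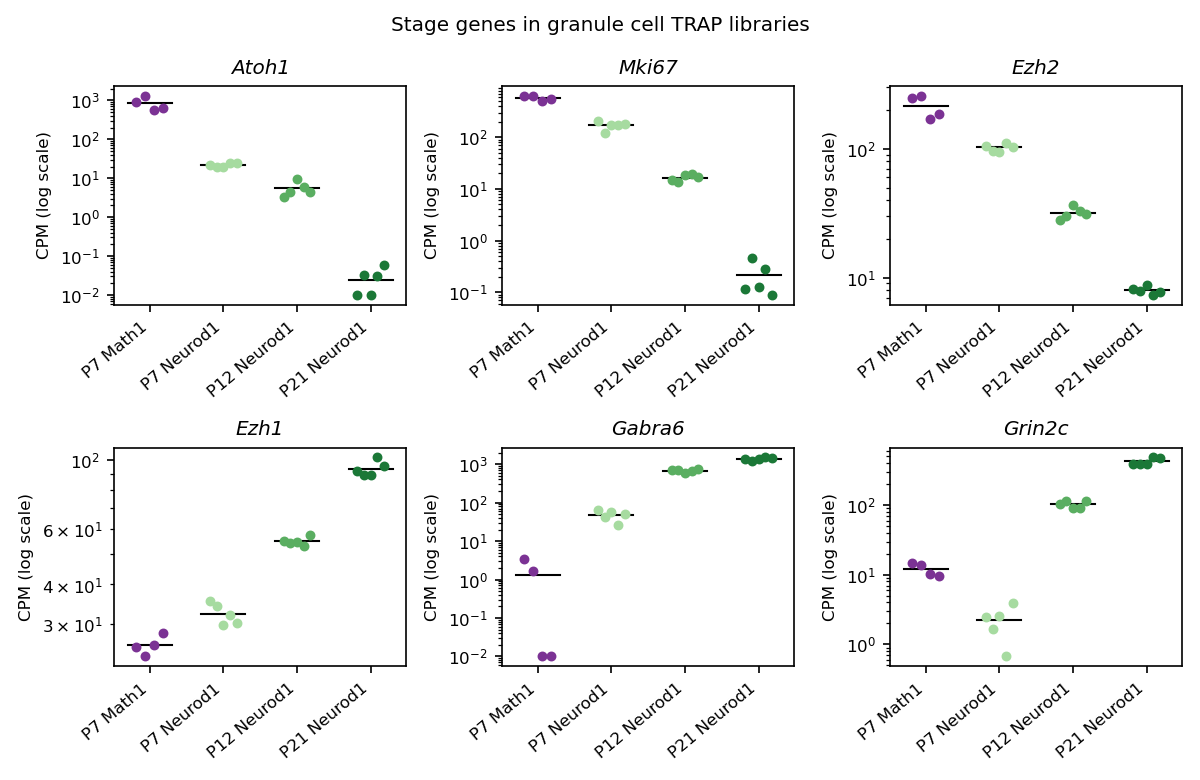
Level of 6 genes in each TRAP library, in counts per M on a log axis (values under 0.01 are drawn at 0.01), for P7 Math1 and for P7, P12 and P21 Neurod1 TRAP; each point is a library and each line the group mean. Ezh2 stepped down with age as Ezh1 stepped up, and Gabra6 and Grin2c rose from P7 to P21 in the Neurod1 line while Atoh1 and Mki67 fell.

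From P7 to P21 all 20 cell cycle genes fell, with a median log2 fold change of -6.35 (Top2a, a topoisomerase of dividing cells, went from 236 ± 49.0 to 0.234 ± 0.061 CPM). Of 15 genes of granule progenitors and the Sonic hedgehog pathway that drives their division, 12 fell and 2 rose (Mycn fell from 102 ± 8.64 to 1.32 ± 0.17 CPM, and Gli2 from 48.6 ± 4.36 to 0.633 ± 0.25 CPM). Of 16 early differentiation and migration genes 14 fell, among them Dcx, a microtubule protein of migrating neurons (703 ± 61.8 to 3.25 ± 0.72 CPM), and Nhlh1 (179 ± 17.6 to 1.15 ± 0.39 CPM). Of 16 mature granule cell genes 15 rose and 1 fell. The NMDA receptor subunit Grin2c rose 189-fold from 2.26 ± 1.20 CPM, and Cbln1, a secreted organiser of parallel fibre synapses, from 920 ± 94.9 to 4186 ± 387 CPM. Synapse genes followed, 18 of 20 higher and 2 lower, led by the vesicle fusion proteins Vamp1 (16.3-fold) and Snap25 (11.3-fold). Of 20 granule transcription factors and chromatin remodelers 15 fell and 4 rose (Bcl11a, 10.1-fold lower). The test of these 6 lists against all other genes (camera) gave adjusted p of 4.0e-10 for the cell cycle, 6.1e-04 for progenitor and 2.5e-04 for early differentiation genes. It gave 2.4e-05 for mature granule cell, 1.6e-04 for synapse and 0.0291 for transcription factor genes. With an estimated correlation none of the 21 lists measured in these libraries passed (smallest adjusted p = 0.323 with an estimated correlation). Adjusted over the list alone the counts of these 6 lists were the same except for 15 early differentiation genes lower.

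Other groups moved without passing the list test. Voltage-gated channels had 10 of 16 members higher and 2 lower (adjusted p = 0.0512), with the sodium channel Scn2a 6.40-fold higher. Polycomb complex genes split, 7 of 22 higher and 11 lower (adjusted p = 0.850). Beside the exchange of Ezh2 for Ezh1, the H3K27me3 readers Cbx7 (3.01 ± 0.44 to 54.4 ± 2.34 CPM, 18.1-fold) and Cbx6 (172 ± 17.5 to 859 ± 32.8 CPM) rose. Of 15 H3K4 methylation enzymes 9 fell and 1 rose (adjusted p = 0.0538), with the demethylase Kdm1a 2.97-fold lower. Among 13 measured developmental regulators that are silenced in most neurons 6 fell and 4 rose (adjusted p = 0.571). The homeobox gene Irx3 rose 12.1-fold and Pax3 fell 9.21-fold. Cholesterol synthesis genes had 10 of 15 members lower and 4 higher (adjusted p = 0.103), with Hmgcs1 3.99-fold lower. Immediate early genes, induced by activity or stress, had 10 of 12 members higher and 1 lower (adjusted p = 0.0515), and varied between the P21 libraries (Nr4a1 142 ± 72.7 CPM). Over the list alone these counts were the same except for 11 cholesterol genes lower. Among the largest rises were those of Cabp2, Crtam, Gprc5c and Grin2c, and the largest falls those of Esco2, Top2a, Kif18b, Mki67 and Ndc80.

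Markers of other cell types also changed between the P7 and P21 pull-downs, none past the list test. Of 8 Purkinje cell markers 6 were higher and 1 lower (adjusted p = 0.0741; Car8 80.6 ± 8.64 to 318 ± 21.9 CPM), of 8 GABAergic interneuron markers 4 higher and 2 lower (0.426). Of 12 oligodendrocyte lineage markers 8 were higher and 3 lower (0.215; the precursor marker Pdgfra fell from 108 ± 8.80 to 1.47 ± 0.15 CPM while myelin Mog rose from 1.82 ± 0.46 to 20.8 ± 4.75 CPM). Of 11 Bergmann glia and astrocyte markers 4 were higher and 4 lower (0.850). Of 10 microglia markers 4 were higher (2 adjusted over the list alone; 0.463), and of 12 vascular and meningeal markers 3 lower (2 over the list alone; 0.822). Of 3 erythrocyte markers 3 were higher (0.195; Hbb-bs 8.25 ± 3.05 to 53.4 ± 13.9 CPM), and of 3 unipolar brush cell markers 1 higher and 1 lower (2 and 1 over the list alone; 0.850). Of 5 sex-linked genes 1 was lower (0 over the list alone), and 3 of 5 P7 libraries held Xist without Ddx3y and 2 the reverse, against 2 and 3 at P12 and at P21.

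Both steps carried large changes. From P7 to P12, 4647 genes were higher and 5421 lower of 14759 tested. Mki67 (10.3-fold), Top2a (11-fold) and the hedgehog effector Gli1 (6.31-fold) fell, while Grin2c (45.6-fold), Gabra6 (14.3-fold), the vesicular glutamate transporter Slc17a7 (7.25-fold) and Snap25 (4.24-fold) rose. Lists past the test were cell cycle (20 of 20 lower, adjusted p = 8.9e-11), mature granule cell (15 of 16 higher, 1 lower, 2.5e-07), synapse (17 of 20 higher, 9.3e-06) and progenitor (12 of 15 lower, 2 higher, 9.9e-04). So were H3K4 methylation enzymes (11 of 15 lower, 0.0092), Purkinje cell markers (8 of 8 higher, 0.0113) and channels (10 of 16 higher, 3 lower, 0.0166). None of them passed with an estimated correlation (smallest adjusted p = 0.264 with an estimated correlation). From P12 to P21, 4784 genes were higher and 4821 lower. Early differentiation genes fell mostly in this step: Dcx was 59.4-fold lower, Nhlh1 72.8-fold and Tubb2b 30.4-fold, and 15 of 16 list members fell (adjusted p = 2.2e-07). The cell cycle (20 of 20 lower, 2.6e-13), progenitor (11 of 15 lower, 2 higher, 1.5e-04), transcription factor (15 of 20 lower, 2 higher, 0.0043) and cholesterol (10 of 15 lower, 2 higher, 0.0113) lists fell too. The mature granule cell (14 of 16 higher, 1 lower, 0.0014), immediate early (10 of 12 higher, 1 lower, 0.0083) and synapse (13 of 20 higher, 2 lower, 0.0095) lists rose (smallest adjusted p = 0.159 with an estimated correlation). Adjusted over the list alone these counts were the same, except for 11 cholesterol genes lower. Neurod1 did not pass from P7 to P12 (2562 ± 139 against 2468 ± 74.7 CPM, adjusted p = 0.56) and fell to 1793 ± 231 CPM at P21 (-0.46 ± 0.08).

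Between P7 and P21, 5748 genes were higher and 6279 lower of 14759 tested by edgeR. The balance depends on how the libraries are scaled. For P21 against P12, 49.8% of the called genes were higher after the TMM composition correction and 35.7% when scaled by library size only, which moved the median of all genes by -0.15 (log2). The same scaling moved it by -0.22 for P21 against P7. Nothing in the labels says that replicates came from separate animals or litters, so every p here measures only the spread between these libraries.

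**Figure D2:**
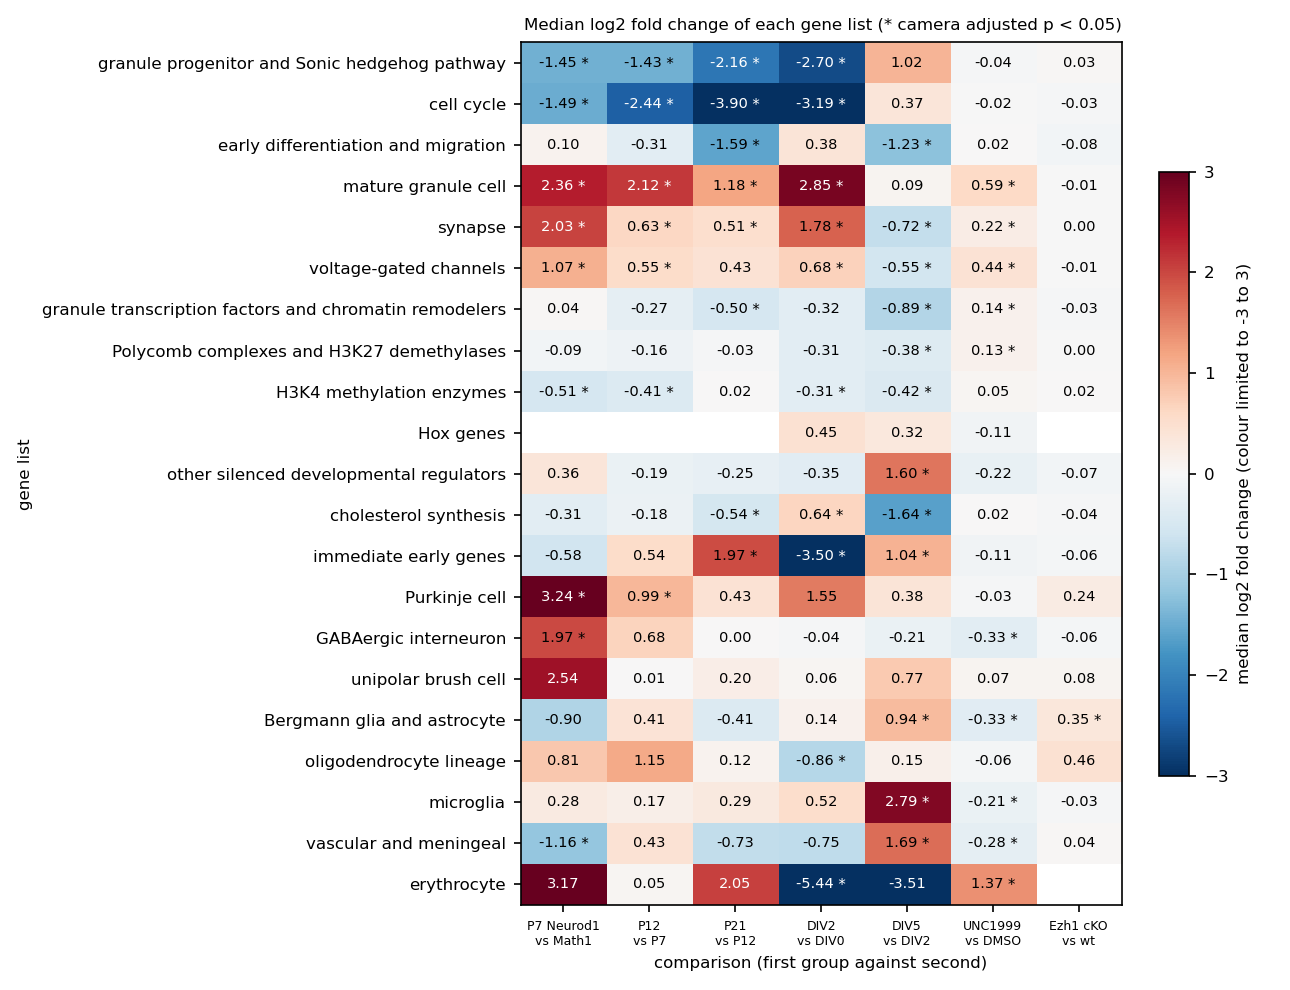
Median log2 fold change of each fixed gene list (1 line per list) in 7 comparisons (1 column each), on a colour scale centred on 0; a star marks a list with a camera adjusted p under 0.05 at the preset correlation. The cell cycle list had a median of -2.44 from P7 to P12 and -3.9 from P12 to P21. The mature granule cell list rose in both of these steps, from DIV0 to DIV2 and under UNC1999 (median 0.59) but not from DIV2 to DIV5 (8 of 16 higher, 8 lower). With an estimated correlation 0 of the list calls passed.

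The comparison of the 2 driver lines at P7 sets progenitors beside differentiating cells of the same age (Neurod1 n = 5, Math1 n = 4). The Math1 libraries held the progenitor state. Atoh1 stood at 863 ± 331 CPM against 22.1 ± 2.77 in the Neurod1 libraries, 39.1-fold apart (log2 fold change -5.29 ± 0.26, adjusted p = 1.3e-12). Mki67 stood at 577 ± 63.5 against 171 ± 32.8, and Ezh2 at 215 ± 44.5 against 102 ± 6.84 CPM (-1.07 ± 0.10). The Neurod1 libraries were higher in Neurod1 (2562 ± 139 against 1140 ± 115 CPM), in Gabra6 (47.9 ± 14.4 against 1.28 ± 1.64 CPM) and slightly in Ezh1 (32.2 ± 2.50 against 25.6 ± 1.78 CPM, 0.34 ± 0.07, adjusted p = 1.3e-04).

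All 15 progenitor and hedgehog genes (Boc 3.46-fold, Gli2 3.87-fold) and all 20 cell cycle genes were lower in the Neurod1 libraries (adjusted p = 9.6e-07 and 5.5e-07). Synapse genes were higher in 18 of 20 cases and lower in 2 (5.2e-07; Shank1, a scaffold of excitatory synapses, 7.93-fold), mature granule cell genes higher in 14 of 16 and lower in 1 (2.8e-05; Chn2 15.8-fold), and channels higher in 12 of 16 and lower in 1 (0.0039; Scn2a 6.25-fold). H3K4 methylation enzymes were lower in 13 of 15 and higher in 1 (7.0e-04; Kmt2d 2.58-fold). These lists gave adjusted p of 0.304 to 0.439 with an estimated correlation. Early differentiation genes divided, with Stmn2 3.83-fold higher and the axon guidance receptor Dcc 5.38-fold lower (4 of 16 each way, 3 each way adjusted over the list alone, 0.909). Other cell types differed between the preparations. Purkinje markers were higher in the whole-cerebellum Neurod1 pull-down (7 of 8, 0.0038; Calb1 61 ± 8.70 against 5.13 ± 3 CPM). So were interneuron markers (6 of 8, 0.0224; Gad1 38.6 ± 5.95 against 5.00 ± 2.46 CPM). Vascular markers were higher in the Math1 libraries (10 of 12, 1 the other way, 0.0148; Cdh5 5.17 ± 1.01 against 0.695 ± 0.26 CPM). These 3 lists gave adjusted p of 0.304, 0.439 and 0.504 with an estimated correlation. Over the list alone the counts of all lists named in this paragraph, early differentiation apart, were the same.

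In total 5391 genes were higher and 5291 lower in the Neurod1 libraries. Beside Atoh1, the largest differences were near-absences in one line. Eno1b (216 ± 16 against 0.473 ± 0.37 CPM), Ccl19, Rit2 and Ankrd34a were higher in the Neurod1 line. Mndal (0.642 ± 0.58 against 60.3 ± 26.1 CPM), Ahcy (2.90 ± 0.73 against 104 ± 13.2 CPM), Eln and Ifi203 were higher in the Math1 line. Eno1b has a near copy, Eno1, and the summed level of the pair had a ratio of 0.883 between the lines. Driver, starting material and mouse line change together here and cannot be separated. The Math1 libraries also fell into the pairs 1 and 2, and 3 and 4: against pair 1 and 2 alone Egr1 turned from a log2 fold change of -3.87 to 0.32, and against pair 3 and 4 alone C1qa turned from -1.38 to 0.60.

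The inputs ask how far the Neurod1 pull-down enriched granule cell RNA (15 TRAP and 3 input libraries, with age in the model). Mature granule cell genes were enriched (10 of 16 higher and 2 lower, adjusted p = 0.0137, but 0.415 with an estimated correlation). Granule progenitor genes (1 of 15 higher and 10 lower, 0.143) and early differentiation genes (5 of 16 higher and 6 lower, 0.912) did not pass as lists. Every measured Purkinje, interneuron, astrocyte, oligodendrocyte, microglia, vascular and erythrocyte marker was lower. Cbln1 was 3.13-fold higher in TRAP (log2 fold change 1.65 ± 0.10, adjusted p = 8.8e-11), Stmn2 2.58-fold, Gabra6 1.95-fold and Neurod1 1.73-fold. The Purkinje marker Calb1 was lower (120 ± 45.5 against 733 ± 171 CPM), as were the astrocyte water channel Aqp4 (28.2 ± 8.86 against 268 ± 82.0 CPM), the interneuron enzyme Gad2 (9.76 ± 1.49 against 61.6 ± 3.94 CPM) and the pericyte gene Rgs5 (9.56-fold). Ezh1 was 1.29-fold higher (0.37 ± 0.06, but -0.03 when scaled by library size only), and Ezh2 (adjusted p = 0.33) and Atoh1 (0.66) did not pass.

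Depleted in TRAP were 8 of 8 Purkinje (adjusted p = 2.8e-04), 8 of 8 interneuron, 11 of 11 astrocyte, 12 of 12 oligodendrocyte and 12 of 12 vascular markers (1.4e-04 each), 11 of 11 microglia markers (0.0012) and 3 of 3 erythrocyte markers (0.0357), with adjusted p of 0.318 to 0.395 with an estimated correlation. Unipolar brush cell markers, from another line of glutamatergic neurons, divided, with Eomes higher (91.4 ± 26.6 against 45.4 ± 10.4 CPM). Mature granule cell genes were higher in 10 of 16 cases and lower in 2 (0.0137), synapse genes higher in 13 of 20 and lower in 4 (0.0466), and Polycomb genes higher in 14 of 22 and lower in 3 (0.0142). Channels were lower in 11 of 16 and higher in 1 (0.0149) and silenced regulators lower in 12 of 17 and higher in 1 (0.0466). The first 2 of these 5 gave an adjusted p of 0.415 with an estimated correlation, Polycomb genes 0.318, and channels and silenced regulators 0.395. Adjusted over the list alone, every count here was the same. The largest falls were those of Lrrc17, Cdr1, Malat1 (37.0 ± 21.1 against 1455 ± 1172 CPM), Meg3 (71.6 ± 46.8 against 1866 ± 1033 CPM) and Mir124a-1hg, and Ttc9b and Edf1 were among the largest rises. Of 15479 genes tested 5667 were higher and 6375 lower in TRAP. Scaled by library size only, 25.6% instead of 47.1% of the called genes were higher and the median of all genes moved by -0.46.

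The DMSO cultures ask how far the same maturation proceeds outside the animal (n = 2 at each time, so each comparison rests on a spread shared over 8 libraries). The 2 DIV0 libraries differed little beyond counting error (chi-square per degree of freedom 1.45, against 7.66 at DIV2, 4.96 at DIV5 and 4.65 with UNC1999). They enter the shared spread, which may therefore understate the spread between separate preparations. From DIV0 to DIV2 cell cycle genes fell and mature granule cell genes rose. Mki67 fell from 1305 ± 29.6 to 53.0 ± 14.3 CPM (log2 fold change -4.64 ± 0.18, adjusted p = 2.6e-06) and Atoh1 from 53.1 ± 1.05 to 0.83 ± 0.050 CPM. Gabrd, a GABA-A receptor subunit of mature granule cells, rose from 0.352 ± 0.053 to 55.7 ± 0.32 CPM (7.31 ± 0.14), Chn2 17.0-fold, Scn2a 12.6-fold and Syn2 7.19-fold. Ezh2 fell 3.43-fold (181 ± 7.33 to 52.9 ± 1.63 CPM), and Ezh1 did not pass (47.6 ± 2.86 and 52.4 ± 3.81 CPM, adjusted p = 0.081).

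At DIV2 all 20 cell cycle genes were lower (adjusted p = 7.4e-09), with 14 of 15 progenitor and hedgehog genes (8.0e-07; Gli1 88.6 ± 0.43 to 0.302 ± 0.041 CPM) and 12 of 12 immediate early genes (4.9e-07; Fosb 155 ± 3.55 to 0.436 ± 0.038 CPM). All 20 synapse genes (9.2e-09), 15 of 16 mature granule cell genes (1.8e-07), 14 of 15 cholesterol synthesis genes (4.8e-04; Hmgcs1 687 ± 15.8 to 1399 ± 36.5 CPM) and 12 of 16 channels (2 lower, 0.0031) were higher. H3K4 methylation enzymes (10 of 15 lower, 2 higher, 0.0343), oligodendrocyte markers (10 of 12 lower, 1 higher, 0.0026) and erythrocyte markers (3 of 3 lower, 0.0478) fell. Adjusted over the list alone these counts were the same. With an estimated correlation the adjusted p of these lists ran from 0.0759 (mature granule cell and synapse) to 0.444. In all 5809 genes were higher and 5589 lower of 15978 tested.

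From DIV2 to DIV5 early differentiation genes fell, and astrocyte, microglia, and vascular and meningeal markers rose. Oligodendrocyte markers divided, 4 of 12 higher and 3 lower (camera adjusted p = 0.376). Neurod1 fell too, from 1728 ± 36.9 to 772 ± 1.38 CPM. Whether granule cells made up a smaller share of the DIV5 cultures was not tested, so these levels do not show a change within granule cells. Nhlh1 fell 13.0-fold, Tubb3, a neuronal tubulin, 7-fold (428 ± 15.7 to 61.1 ± 1.48 CPM) and Dcx 5.05-fold. Microglial Ctss rose from 18.5 ± 2.75 to 145 ± 9.62 CPM and Csf1r from 21.3 ± 2.30 to 148 ± 5.17 CPM, astrocytic Aqp4 from 216 ± 5.82 to 635 ± 6.39 CPM, and the interferon-response genes Iigp1, Ifit3, Oasl2 and Ifit1 were among the 5 largest rises (Ifit3 0.347 ± 0.023 to 61.6 ± 0.88 CPM). Mature granule cell genes divided, 8 of 16 higher and 8 lower (adjusted p = 0.944): Gabra6 (7.31 ± 0.14 to 16.2 ± 0.97 CPM) and the glutamate receptor Grm4 (163 ± 13.7 to 361 ± 11 CPM) rose, and Kcnc1 and Camk4 fell 2.13-fold and 2.03-fold. Mki67 rose to 97.8 ± 3.67 CPM (0.90 ± 0.17, adjusted p = 0.0048) within a cell cycle list of 9 of 20 members higher and 2 lower (0.0721).

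All 16 early differentiation genes (adjusted p = 5.0e-08), 15 of 15 cholesterol genes (5.9e-08; Hmgcs1 5.35-fold), 18 of 20 transcription factors (2 higher, 2.2e-05) and 18 of 20 synapse genes (2.2e-05; 19 adjusted over the list alone) fell from DIV2 to DIV5. So did 12 of 15 H3K4 methylation enzymes (6.0e-04; 13 over the list alone), 14 of 22 Polycomb genes (2 higher, 0.0182) and 11 of 16 channels (3 higher, 0.0300). Higher were 11 of 11 microglia (1.6e-06), 11 of 11 astrocyte (4.7e-05) and 9 of 12 vascular and meningeal markers (7.5e-04), 10 of 12 immediate early genes (3.5e-04) and 14 of 21 silenced regulators (1 lower, 0.0026; Bmp4 8.13-fold). The smallest adjusted p was 0.104 with an estimated correlation, and the other list counts were the same adjusted over the list alone. By edgeR 4966 genes were higher and 5699 lower, 46.6% higher, against 57.4% higher when scaled by library size only.

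Over the whole culture, DIV5 against DIV0, Gabrd rose to 103 ± 4.86 CPM and Grm4 from 5.16 ± 0.32 CPM (69.5-fold). Dcc fell from 509 ± 8.20 to 3.90 ± 0.54 CPM, and Ezh2 fell 5.80-fold. Ezh1 rose 1.12-fold (0.16 ± 0.07, adjusted p = 0.046), a call lost without DIV0 library 2 (log2 fold change 0.11), without DIV5 library 1 (0.16) or 2 (0.14), with DESeq2 size factors (0.15), without a filter on low counts (0.16) and under the DESeq2 test (0.15). The cell cycle (20 of 20 lower, adjusted p = 2.5e-07), progenitor (14 of 15 lower, 1.7e-05), immediate early (12 of 12 lower, 1.7e-05) and H3K4 methylation (15 of 15 lower, 5.7e-05) lists fell. So did the transcription factor (17 of 20 lower, 2 higher, 9.5e-05), cholesterol (14 of 15 lower, 1 higher, 1.1e-04), early differentiation (12 of 16 lower, 3 higher, 0.0025) and Polycomb lists (15 of 22 lower, 6 higher, 0.0106). The mature granule cell (15 of 16 higher, 3.4e-06), synapse (20 of 20 higher, 4.1e-06) and microglia lists (11 of 11 higher, 1.1e-04) rose (smallest adjusted p = 0.0763 with an estimated correlation). Adjusted over the list alone these counts were the same. Of the blood genes, Hbb-bs was counted at 38.3 ± 0.15 CPM at DIV0 and 0 times at DIV5, at least 484.5-fold lower with 3 counts over the group as the floor (a bound on counting error only), and 3 of 3 erythrocyte markers fell (0.0346; adjusted p = 0.188 with an estimated correlation). In all 6422 genes were higher and 6096 lower, and scaling by library size only moved the median of all genes by 0.15.

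Genes of maturation in the animal behaved partly alike in culture. Of 14428 genes tested in both, 9605 were called in both P21 against P7 and DIV5 against DIV0, and 6877 of these (71.6%) changed in the same direction. Both higher were 3149 (2212.5 if independent) and both lower 3728 (2521.6), against 1277 (2299.2) and 1451 (2426.4) in opposite directions. Genes shared with the smallest p were Gabrd, Chn2, Adap1, Scn2a and Adora1 (higher) and Nhlh1, Insm1, Ebf3, Rcor2 and Dcc (lower). The log2 fold changes correlated with a Pearson r of 0.41 and a Spearman rho of 0.41 across genes, which are not independent replicates. For DIV5 against DIV2 r was 0.10 and 57.6% of the 8221 genes called in both had the same sign. Genes shared there included the lysosomal enzymes Ctsd, Ctsa, Ctsb and Tpp1 (higher) and Tubb3, Hmgcs1 and Tubb2b (lower). Of the 2642 measured genes that rose at least 2-fold from P7 to P21, 1556 were higher and 433 lower at DIV2 than DIV0, and 1130 higher and 611 lower at DIV5 than DIV2 (adjusted p = 2.1e-10 and 4.1e-04, and 3.1e-04 and 0.0025 with an estimated correlation). Of the 3257 that fell, 1935 were lower and 708 higher at DIV2 (2.1e-10, and 0.0379 with an estimated correlation), whereas from DIV2 to DIV5 1340 were lower and 1071 higher (0.402).

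UNC1999 asks what granule cells do at DIV5 when EZH2 and EZH1 are inhibited (n = 2 with UNC1999, n = 2 with DMSO). Genes that mark mature granule cells were higher with the inhibitor. Gabra6 stood at 60.2 ± 2.02 against 16.2 ± 0.97 CPM, 3.73-fold higher (log2 fold change 1.90 ± 0.09, adjusted p = 1.1e-07), and Grin2c at 47.1 ± 5.52 against 11.8 ± 1.25 CPM, 3.97-fold higher (1.99 ± 0.12, adjusted p = 8.1e-07). Grm4 (654 ± 44.6 against 361 ± 11 CPM), Chn2 (288 ± 4.90 against 172 ± 7.18 CPM) and the calcium sensor of vesicle release Syt1 (345 ± 22.9 against 203 ± 3.70 CPM) were higher too. Some markers of other cells in the same cultures were lower, among them microglial Ctss (88.4 ± 0.17 against 145 ± 9.62 CPM), glial Slc1a2 (122 ± 0.98 against 167 ± 13.9 CPM) and interneuron Slc32a1 (20.4 ± 0.89 against 28.6 ± 0.13 CPM). Ezh1 (59.6 ± 0.29 against 53.2 ± 0.62 CPM, adjusted p = 0.15), Ezh2 (31.5 ± 2.11 against 31.1 ± 2.97, 0.93) and Mki67 (88.6 ± 0.95 against 97.8 ± 3.67, 0.65) did not pass.

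**Figure D3:**
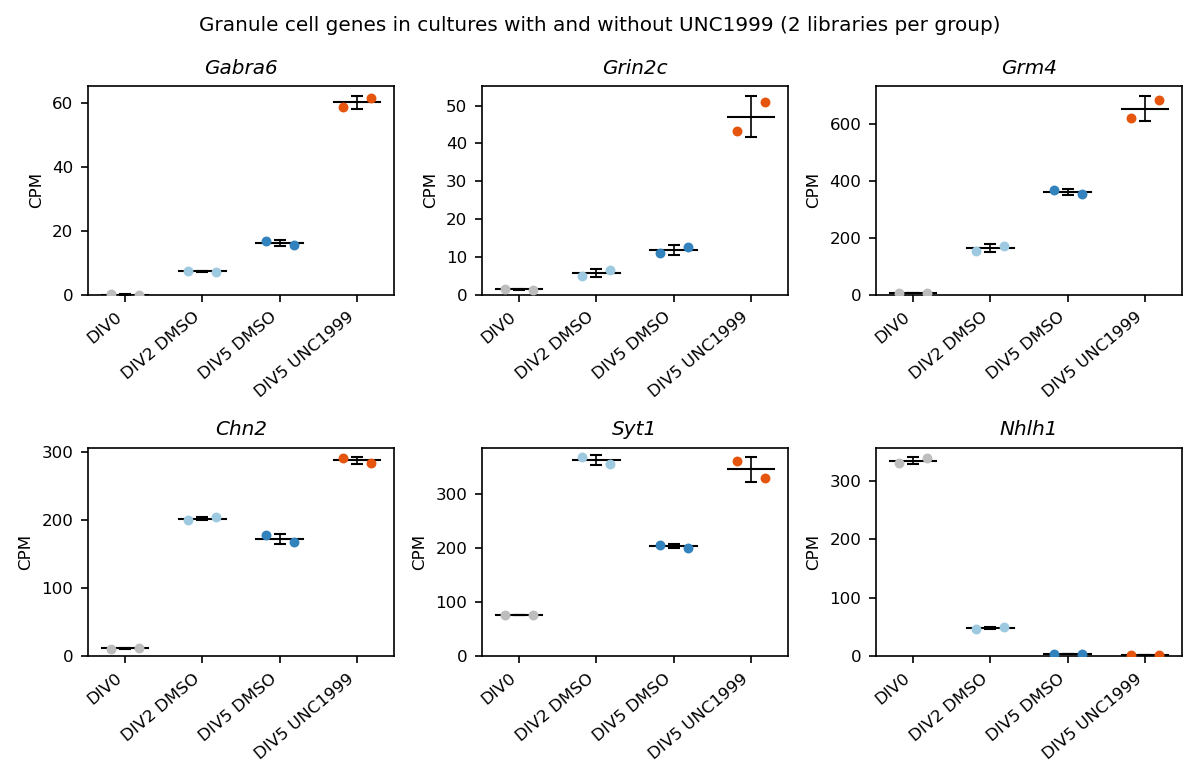
Level of 6 genes in each culture library, in counts per M, at DIV0, DIV2 and DIV5 with DMSO and at DIV5 with UNC1999; points are libraries, and bars the mean ± SD of 2. Gabra6 reached 60.2 ± 2.02 CPM with UNC1999 against 16.2 ± 0.97 with DMSO, while Nhlh1 was lower with UNC1999 (1.46 ± 0.03 against 3.66 ± 0.38 CPM).

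Of 16 mature granule cell genes 12 were higher and 0 lower with UNC1999 (median log2 fold change 0.59, adjusted p = 1.2e-10). Among 20 synapse genes 12 were higher (15 adjusted over the list alone, 1.4e-07; Shank1 1.39-fold, Unc13c 1.69-fold), among 16 channels 11 higher and 1 lower (12 and 1 over the list alone, 2.0e-07; Kcna2 1.67-fold). Among 20 transcription factors 5 were higher and 2 lower (13 and 2 over the list alone, 0.0017; Zic1 1.41-fold, Neurod1 1.28-fold). Polycomb genes were higher in 5 of 22 cases (6 over the list alone, 0.0015; Cbx7 1.81-fold, Bmi1 1.38-fold). The adjusted p of these lists were 0.0699, 0.0717, 0.0720, 0.0721 and 0.0925 with an estimated correlation. Astrocyte markers were lower in 7 of 11 cases (8 over the list alone, 3.0e-06; adjusted p = 0.0721 with an estimated correlation), interneuron markers in 4 of 8 (5 over the list alone, 8.9e-04; 0.0721 with an estimated correlation). Microglia markers were lower in 4 of 11 with 1 higher (6 and 1 over the list alone, 0.0098; adjusted p = 0.332 with an estimated correlation) and vascular markers in 2 of 12 (2 over the list alone, 0.0237; adjusted p = 0.475 with an estimated correlation). The erythrocyte list passed as higher with 0 of 3 genes called, all near 0 counts (0.0378; adjusted p = 0.203 with an estimated correlation).

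Few measured members of the lists of Hox genes and other silenced regulators passed with UNC1999. Members with too few counts in the culture libraries were not tested, so a small rise of a silent gene would be missed. Some measured members were not silent at DIV5 with DMSO, such as Bmp4 (36.8 ± 0.87 CPM) and Tlx3 (26.8 ± 0.22 CPM). None of the 4 measured Hox genes passed (adjusted p = 0.589 for the list, all under 1 CPM), and of 21 other silenced regulators Tlx3 was 1.28-fold higher and Bmp4 1.33-fold lower (0.105; 1 higher and 0 lower adjusted over the list alone). Cell cycle (1 of 20 lower, 0 over the list alone, 0.510), progenitor (1 of 15 higher and 2 lower, 1 and 3 over the list alone, 0.471; Gli1 0.314 ± 0.10 against 0.998 ± 0.087 CPM), early differentiation (2 of 16 each way, 0.589), cholesterol (0 of 15, 0.471), immediate early (0 of 12, 0.264) and H3K4 methylation genes (2 of 15 higher, 0.105) did not pass as lists. Nor did Purkinje (1 of 7 lower, 0.310), oligodendrocyte (1 of 12 higher, 0.287), unipolar brush cell (1 of 3 higher, 0.105) and sex-linked markers (1 of 5 higher, 0.313). The unipolar brush cell gene Eomes was among the 5 largest rises (31.3 ± 0.65 against 11.7 ± 0.33 CPM) with Hrk, and Col24a1, AI593442, Myo1a, Folr2 and Ass1 fell most.

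In all 1016 genes were higher and 883 lower with UNC1999 by edgeR, 125 of them at least 2-fold, against 930 by DESeq2. On data simulated once for this design with 200 changed genes, 23 of 189 calls (12.2%) were unchanged genes. The count was 932 without UNC1999 library 2, 939 without DMSO library 1 and 1098 without UNC1999 library 1, and 15 of the 57 named calls were lost under at least one alternative, among them Ptch1, Gad1, Gad2, Csf1r, Cx3cr1, Cldn5, Tlx3 and Bmp4.

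Set beside maturation in the animal, genes that rose from P7 to P21 leaned higher with UNC1999 (340 higher and 128 lower of 2642, median log2 fold change 0.03, adjusted p = 0.0361, and 0.0200 with an estimated correlation). Genes that fell leaned lower (265 lower and 158 higher of 3257, -0.05, adjusted p = 0.0152, but 0.276 with an estimated correlation). Without DMSO library 1 both gave 0.121 and without UNC1999 library 2 both gave 0.101. Across all 14428 genes r was 0.13 and rho 0.14, against 0.33 and 0.33 in the 1498 called in both, of which 960 (64.1%) changed in the same direction. Both higher were 544 (393.07 if independent), with Gabra6, Unc80, Grin2c, Kirrel3 and Syt1 first, and both lower 416 (333.34), with AI593442, Angptl4, Ptprk and Cd9 first, against 205 (303.94) and 333 (431.08) in opposite directions.

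The Ezh1 cultures ask whether loss of Ezh1 alone changes granule cells at DIV5 (cKO n = 4, wt n = 5). The targeted gene was read at 35.4, 36.6, 35.1 and 33.3 CPM in the 4 cKO libraries and at 42.7, 43.3, 49.3, 47.0 and 39.4 CPM in the 5 wt libraries, lower in 4 of 4 but by only 1.26-fold on average (35.1 ± 1.39 against 44.3 ± 3.89 CPM, log2 fold change -0.34 ± 0.09, adjusted p = 1.0). Counts per gene do not show whether particular exons were lost. No gene passed between the genotypes: edgeR called 0 of 14461 (169 at an unadjusted p under 0.05) and DESeq2 0. The 169 are a smaller share than the 0.05 that unchanged genes would give. This edgeR fit counted a difference between sets of libraries, described below, as spread. Its 0 calls therefore do not show that genotype had no effect. With the set as a term 1145 genes had an unadjusted p under 0.05 by edgeR, a larger share, but that fit has no term for replicate number. Gabra6 (28.4 ± 9.76 against 23.7 ± 12.9 CPM), Ezh2 (52.4 ± 6.05 against 52.7 ± 6.86), Neurod1 (931 ± 316 against 993 ± 355) and Mki67 (96.9 ± 15.1 against 80.5 ± 18.9) were within the spread of the libraries, which includes the difference between the sets. With the set term Gabra6 and Ezh2 did not pass either (edgeR adjusted p = 0.62 and 0.938).

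**Figure D4:**
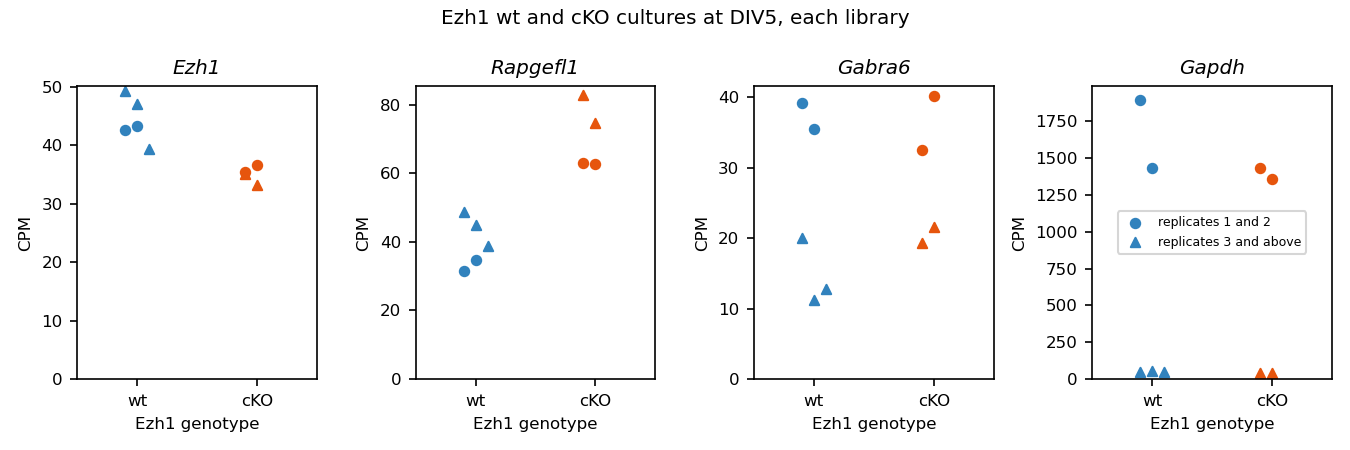
Level of 4 genes in each Ezh1 library, in counts per M, by genotype; circles are replicates 1 and 2 and triangles replicates 3 and above. Ezh1 was lower in every cKO library than in any wt library, Rapgefl1 was higher in every cKO library, and Gapdh separated the replicates (1362 CPM or more in replicates 1 and 2, 40.4 to 54.0 CPM in the others) in both genotypes.

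The 9 libraries fell into the sets of replicates 1 and 2 and replicates 3 to 5, each holding both genotypes. Correlations of log2 CPM were 0.990 to 0.996 within a set and 0.962 to 0.973 across. Of 14461 genes 9271 differed between the sets, and 11 genes with at least 20 CPM in the first set had 0 counts in the second. With the set as a term, a fit added after these data were seen, 1 gene passed: Rapgefl1 was 70.7 ± 9.81 CPM in cKO against 39.7 ± 7.13 in wt (0.88 ± 0.08, adjusted p = 0.0062), 62.7 against 33.1 CPM in the first set and 78.7 against 44.2 CPM in the second. This call was lost with replicate number as a block, where edgeR called 0 genes (1430 at an unadjusted p under 0.05) and Rapgefl1 had a log2 fold change of 0.84 (adjusted p = 0.0779). As deviations of log2 CPM from the group mean, wt and cKO libraries of the same number correlated at 0.832 to 0.914 in 4 pairs, which follows the sets too, and 3 of the 4 were closest to their own number. Rapgefl1 lies 2.34 Mb from Ezh1 on chromosome 11. Ezh1 then had a log2 fold change of -0.34 ± 0.08 (adjusted p = 0.578). Without the set term only astrocyte markers passed of 19 lists, higher in cKO (median log2 fold change 0.35, 0 of 11 members called, 0 adjusted over the list alone, adjusted p = 0.0033, but 0.990 with an estimated correlation). Among them Aqp4 stood at 2257 ± 613 against 1464 ± 848 CPM. The astrocyte list also passed as higher with the set term (median 0.26, camera adjusted p = 0.0019, but 0.842 with an estimated correlation). With replicate number as a block it passed too (camera adjusted p = 2.4e-04). Immediate early genes passed as lower with the set term (0 of 12 called, adjusted p = 0.0364, but 0.842 with an estimated correlation). They did not pass without it (0.223) or with replicate number as a block (0.0668). Every other list had 0 members called, over all genes and adjusted over the list alone. Most genes on X and Y were blank in these 9 libraries (1012 on X and 28 on Y, with 1 unmatched gene) and were not tested, while 12 on X and 11 on Y held values.

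Genes that rose from P7 to P21 did not lean either way in cKO cultures (adjusted p = 0.979), and genes that fell from P7 to P21 leaned slightly higher (median log2 fold change 0.03, adjusted p = 0.0094, but 0.232 with an estimated correlation). That call ended without wt library 1 (0.277), cKO library 3 (0.0894) or cKO library 4 (0.0883).

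The difference between the UNC1999 and the Ezh1 cKO effect was tested in one fit of 13 libraries. That fit had no term for the 2 sets of Ezh1 libraries or for replicate number, so the difference between the sets counts as spread. No single gene passed by edgeR (247 of 15453 at an unadjusted p under 0.05, smallest adjusted p 0.531; DESeq2 was not run on this contrast), and with Ezh1 replicates 3 to 5 alone 4 did. As lists, mature granule cell genes rose more with UNC1999 than with cKO (median difference 0.50, adjusted p = 4.6e-08; 2 members adjusted over the list alone), as did channels (0.34, 0.0015), Polycomb (0.13, 0.0026) and synapse genes (0.30, 0.0205), and astrocyte markers went lower (-0.66, 1.7e-04). With an estimated correlation none of the 19 lists passed (adjusted p = 0.0890 with an estimated correlation for mature granule cell genes).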

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

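The tests of explanations in this part were chosen after the results were seen. The tests of the difference between the UNC1999 and the Ezh1 cKO effect were chosen before.

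The total count of 1 library stood far from its group. P7 Neurod1 TRAP library 1 held 38 M counts, against 23.9 to 27.6 M in the other 4. Of 40 groups of values tested for such a gap 1 had it, and chance gives it in about 1 of 20.

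The effects of UNC1999 and of Ezh1 cKO differed for 5 gene lists and for both sets of in vivo maturation genes. Mature granule cell genes rose more with UNC1999 (camera adjusted p = 4.588e-08), as did voltage-gated channels (0.001498), Polycomb genes (0.002613) and synapse genes (0.02053), while astrocyte markers went lower (0.000174). Genes higher at P21 than P7 leaned higher with UNC1999 than with cKO (0.01247), and genes lower at P21 leaned lower (2.694e-05). With an estimated correlation none of these passed, the nearest being genes lower at P21 (0.0513) and mature granule cell genes (0.0890). The 2 effects come from separate experiments on mice of different genotype, and only the Ezh1 libraries fall into 2 sets, so the difference of effects is not tied to the enzymes alone.

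The rise of mature granule cell genes under UNC1999 came with a fall of astrocyte (7 of 11), interneuron (4 of 8) and microglia markers (4 of 11, with 1 higher). As lists these markers no longer passed with an estimated correlation (camera adjusted p = 0.0721, 0.0721 and 0.332), a setting that does not touch the calls of single genes. The fall of these markers raises the question of whether granule cells only made up a larger share of those cultures. The median log2 fold change was 0.59 for the 16 mature genes and 0.02 for the 16 early differentiation genes, a difference of 0.57 (permutation p = 1e-05, the smallest that 1e+05 resamples of genes can give, and genes are not independent). This would count against a larger share only if early genes followed granule cell RNA, but in TRAP against input the mature genes had a median of 0.98 and the early ones of -0.06, so a larger share stays open. All 12 called mature genes stayed called without each of the 4 libraries in turn, 12 of 12, which argues against a single library as the cause. A change in maturation through H3K27me3 may stand behind the pattern, as may a loss of other cells that acts on granule cells. These were not tested.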

How the results depend on the processing

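The 2 sets of Ezh1 libraries as a term, Ezh1 and Math1 libraries taken in part, the in vivo sets with libraries left out and the crossed block were chosen after the results were seen. The other alternatives were chosen before.

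Counts of called genes stayed within 1.5 times their value for the 8 TRAP, input and DMSO culture comparisons under every alternative run except the demand for a 2-fold change. That demand left 2916 genes for P12 against P7, 2639 for P21 against P12, 6122 for P21 against P7, 3894 between the TRAP lines, 4759 against input, 4876 for DIV2 against DIV0, 3615 for DIV5 against DIV2, 6235 for DIV5 against DIV0 and 125 for UNC1999, since it asks for a larger change. For UNC1999 the DESeq2 test called 930, and leaving out a library gave 932 to 1297: 932 without UNC1999 library 2, 939 without DMSO library 1 and 1098 without UNC1999 library 1. In these fits the lone library of an arm is assumed to vary like the other groups.

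With replicate number as a block the counts were 10093, 9610 and 12012 for the 3 TRAP age comparisons, 10624 between the lines, 11226, 10478 and 12402 for DIV2 against DIV0, DIV5 against DIV2 and DIV5 against DIV0, 1546 for UNC1999 and 0 for Ezh1 cKO (1430 at an unadjusted p under 0.05). Crossing the DIV2 numbers in the block gave 10923 for DIV5 against DIV2. Ezh1 cKO had 1 gene with the 2 sets as a term, and the difference of effects 4 with Ezh1 replicates 3 to 5 alone. The cause was not tested for either. Of the 92 list tests past the threshold 0 were past it with an estimated correlation. That setting widens the error of a list whose genes vary together. It also takes the residual degrees of freedom of the fit in place of those from the number of genes. Taken alone, this raises p where libraries are few. The mature granule cell list under UNC1999, with an estimated correlation of 0.0244, went from a camera adjusted p of 1.2e-10 to 0.0699. Calls were also lost where the estimated correlation was negative. Under UNC1999 the transcription factor list (-0.0228) went from a camera adjusted p of 0.0017 to 0.072. The interneuron list (-0.0468) went from 8.9e-04 to 0.072. A lost call therefore does not show by itself that the genes of a list vary together.

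Genes higher at P21 were no longer past the threshold under UNC1999 without DMSO library 1 (0.121) or UNC1999 library 2 (0.101), with 0.0192 the lowest of the 4. Genes lower at P21 gave 0.121 and 0.101 without the same libraries, 0.0057 at the lowest, and 0.276 with an estimated correlation. In Ezh1 cKO the direction of genes higher at P21, which was never past the threshold, turned with the replicate block (0.178), without cell cycle and other cell type markers (0.985), with the 2 sets as a term (0.597, and 0.748 with an estimated correlation), and without wt library 4 (0.527), wt library 5 (0.145), cKO library 1 (0.453) or cKO library 2 (0.399), within a range of 0.117 to 0.995 over the libraries left out. Genes lower at P21 lost their call in Ezh1 cKO with an estimated correlation (0.232, and 0.394 with the term), and without wt library 1 (0.277), cKO library 3 (0.0894) or cKO library 4 (0.0883), with 5.2e-05 the lowest. Their adjusted p with the replicate block was 4.1e-05. The cause was not tested.

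Across genes, Pearson r between maturation in the animal and in culture was 0.49 (Spearman 0.49) for genes called in both and 0.10 (Spearman 0.13) for DIV5 against DIV2. Of the named genes 3 turned: Egr1 between the TRAP lines with Math1 libraries 1 and 2 alone (0.32), C1qa with libraries 3 and 4 alone (0.60) and Ezh1 against input when scaled by library size only (-0.0295). The cause was not tested. Of 763 named gene results 703 kept direction and side of the threshold throughout. Depth limits genes near 0 counts, such as Hox genes and hemoglobin in culture.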

Other observations

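The tests of explanations in this part, and the counts over other splits, were chosen after the results were seen.

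Of 15 cholesterol synthesis genes 14 were higher at DIV2 than DIV0 and 15 lower at DIV5 than DIV2, but neither list call held with an estimated correlation (adjusted p = 0.444 and 0.190). From P7 to P21 the list did not pass (0.103). Hmgcs1, the enzyme before the controlled step of the pathway, stood at 687 ± 15.8 CPM at DIV0, 1399 ± 36.5 at DIV2 and 262 ± 5.16 at DIV5, while in the animal it fell from 466 ± 25.9 at P7 to 117 ± 10.7 CPM at P21. Sex-linked genes separated the Neurod1 TRAP libraries: at 1 CPM, 7 of 15 held Xist without Ddx3y and 8 Ddx3y without Xist, while all 3 inputs, 4 Math1 libraries and 8 culture libraries held both.

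Genes close to Ezh1 differed between the cKO and wt cultures more often than others. With the 2 sets of libraries as a term, 13 of 276 tested genes within 10 Mb of Ezh1 (4.71%) had an unadjusted p under 0.01, against 0.909% of 14184 genes elsewhere (Fisher's exact test, p = 3.3e-06). At an unadjusted p under 0.05 the excess was smaller, 13.8% against 7.80% (Fisher's exact test, p = 9.6e-04). Both shares come from a fit that ignores the numbered pairs of wt and cKO libraries. They were not taken with replicate number as a block, which lost the call of Rapgefl1. Of the 50 genes with the smallest p 16 lie on chromosome 11, which holds 8.40% of the genes tested, and Rapgefl1 lies 2.34 Mb from Ezh1. A candidate explanation is a chromosome segment from another mouse line carried along with the floxed allele, which would affect neighbours whatever Ezh1 does. A local effect of the altered Ezh1 gene stays open and was not tested.

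Between the P7 TRAP lines 38 genes differed at least 16-fold, 5 lower and 33 higher in the Neurod1 line. Whether maturation switches the lower genes off stays open: 4 of the 5 (Mndal, Ahcy, Eln and Ifi203) were at least 4-fold higher at DIV5 than in the P7 Neurod1 libraries, but they were picked for their low level there, and markers of other cells rose in those cultures from DIV2 to DIV5 (11 of 11 microglia and 11 of 11 astrocyte markers). Reads counted as in the second set of Ezh1 libraries would leave the 11 genes absent there low in the Neurod1 line, but their median log2 fold change was 0.73 (quartiles -0.29 and 0.93), which argues against it for these 11 genes. Eno1b moved the same way between the sets (4.16 to 437 CPM, a ratio of 105, with Eno1 at 1009 and 38.7 CPM) as between the lines (0.483 CPM in Math1 and 224 in Neurod1), so for Eno1b it stays open. Reads of a gene assigned to its near copy may account for Eno1b, since the sum with Eno1 was alike in both lines (ratio 0.883). For Ahcy the sum with its near copy Gm4737 was not alike in the lines (0.410). In the P7 input, however, Ahcy stood at 3.01 and Gm4737 at 64.1 CPM, against 58.9 and 20.8 CPM at DIV0. The copy was thus higher where Ahcy was low, and for Ahcy this explanation stays open. Ahcy, Mndal, Ifi203, Rec8 and AA388235 were at least 4-fold lower in the 18 Neurod1 line libraries, inputs included, than in the 12 others of the table outside the Ezh1 cultures. For these a variant of the mouse line stays open and was not tested. Another 23 genes were higher, among them the Purkinje markers Car8, Pcp2 and Ppp1r17. The 18 libraries come from whole cerebellum and the 12 others from isolated progenitors or their cultures. Starting material and a variant therefore cannot be told apart for the 23.

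Other splits of the same libraries, 60 drawn of those possible, show how large a count an arbitrary split can give. The real count was the largest for P12 against P7 (10068 genes, at most 634 in another split, 1 of 60 as large), P21 against P12 (9605, at most 2662, 1 of 60), P21 against P7 (12027, at most 3513, 1 of 60), the 2 TRAP lines (10682, at most 8452, 1 of 60) and TRAP against input (12042, at most 988, 1 of 60). These splits take the libraries as independent, which the labels do not show, and the Math1 libraries form 2 pairs. They cannot exclude a cause shared by all libraries of an age or a line. The split with 8452 set the 4 Math1 libraries and 1 Neurod1 library against the other Neurod1 libraries. For Ezh1 cKO the real count is 0, so 60 of 60 splits are as large by construction and say nothing about chance. The split into replicates 1 and 2 and replicates 3 to 5 called 9173, a structure of the libraries and not of the genotype. With the 2 sets as a term the real split called 1 gene and the others at most 0 (1 of 60), but these splits ignore the numbered pairs. Only 16 splits part the 4 pairs, too few for a share under 0.05, and with replicate number as a block the count was 0.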
